A study of Mus musculus with 13 samples.

How the data were processed

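Messenger RNA was measured in cultured prostate progenitor/stem cells from 10 wk old wild-type mice at passage 22. At 70% confluency cultures received 100 nM 1,25-dihydroxyvitamin D3 (1,25D) or its solvent, ethanol at 0.1%, as vehicle. Exposure lasted 6 h, or 48 h with daily renewal, per the labels' protocols. For each sample, 5 ug of total RNA was made into biotin-labelled cRNA and hybridised to an Affymetrix mouse array. The 4 groups were vehicle 6 h (3 arrays), 1,25D 6 h (3), vehicle 48 h (3) and 1,25D 48 h (4). Group and replicate came from sample titles; in the descriptions of treated replicates after the first, the digit at the end of the hormone's name counts upward, and the name in titles and source labels was used.

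The authors' deposited values are on a log2 scale, between about 3.05 and 14.45, with medians of 5.573 to 5.668 and upper quartiles of 7.516 to 7.872 over the 13 arrays. The submitters' processing notes name only MAS5, with no version or role; background correction and normalization are otherwise not given in the sources used here. Detection calls were not used, so whether a gene was detected is not known, and folds of dim genes may be understated. Before the data were examined, linear values with an offset of 16 had been assumed; since the values were already in log2, they were used as given with no offset, and offsets were tried as alternatives. The table holds 45101 probe sets, the number of a whole-genome array, whereas the design text names the smaller A chip of that family; names came from the platform annotation given for the table. Of 45037 probe sets left after 64 control sets were removed, 34945 had 1 gene symbol, 932 had several and 9160 had none. Each of 18193 genes was represented by the probe set with the highest mean over the 13 arrays, and none was named from a probe set with several genes; 34741 entrez identifiers matched the GRCm38.p6 gene table, which was used only for names, and no symbol needed updating. No named gene had another probe set called the opposite way. No genome coordinates are given, because the array's build is not stated in the sources used here.

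Group means were fitted over all 13 arrays in limma 3.58.1 (R 4.3.3), with moderated tests (eBayes with an intensity trend, two-sided) of 1,25D against vehicle at 6 h and at 48 h, of the difference between these responses, and of vehicle at 48 h against 6 h. P-values were adjusted by Benjamini-Hochberg over all 45037 probe sets, and a gene was called at an adjusted p under 0.05. Rose, fell, higher and lower refer to calls. Changes are log2 differences of group means. Cyp24a1, Vdr and Il1a were also compared by two-sided exact permutation tests of the difference of means (scipy 1.17.1, Python 3.11.15); figures were drawn with matplotlib 3.10.9. The scripts were tested on simulated data made from the real probe means and spreads over 18193 genes. At 6 h, 73 of 100 genes with a log2 change of 1 and 98 of 100 with a change of 2 were recovered, and at 48 h 82 and 99, with 2 false calls at each time. The simulated noise was independent between arrays and equally wide in all of them. Arrays that are noisier or deviate alike, as in the real data, were not simulated.

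For 30 gene lists of pathways and cell types, fixed from textbook knowledge before the data were examined, 865 of 929 list entries were measured under their symbol and the rest were not analysed here. Lists included markers of stromal, immune, endothelial and neuroendocrine or nerve cells. Each list was tested with limma's camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry, adjusted over the 30 lists of a comparison. Camera compares a list with all other genes, whereas fry asks whether a list's genes move, on balance, one way. Genes named at 6 h and 48 h were the 10 largest rises and falls among called genes whose arrays did not overlap, Cyp24a1, Vdr and Il1a, and up to 4 members with the smallest p of each list described. For the difference and for time in vehicle, the 5 largest in each direction and the same list members were taken; predicted genes were skipped, and exceptions are stated. The fit, the lists, the naming rule and most alternatives were set before the data were examined.

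Alternatives were offsets, quantile normalization, median centring, no or robust intensity trend, leaving out dim probe sets (lowest 40%), fitting only the 2 groups compared, array quality weights, the replicate number as a block, a fold change of at least 1.5, leaving out probe sets that can match several transcripts, and leaving out each array in turn. Added after the data were seen were an offset of 16, leaving out the 2 arrays that stand apart, and leaving out vehicle 48 h replicate 2, whose deviations correlated with those of the 2 arrays, as well. All 13 arrays were used unless stated.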

Results

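Gene expression was measured on 13 arrays of RNA from cultured prostate progenitor/stem cells derived from adult mice. Cells received vehicle (ethanol) or 100 nM 1,25-dihydroxyvitamin D3, written 1,25D below, the hormonal form of vitamin D that acts through the vitamin D receptor. RNA was taken after 6 h as 3 vehicle and 3 treated samples, and after 48 h as 3 vehicle and 4 treated samples. Each RNA was hybridised to 1 oligonucleotide array, and 45037 probe sets were tested, which gave 1 value for each of 18193 named genes. Signals ran from about 3.05 to 14.45 on the log2 scale. The number of arrays limits the precision. The labels do not say whether replicates were separate cultures or dishes of 1 culture, so every p-value below measures only the spread between these arrays.

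The main difference between arrays was that between 6 h and 48 h: the first principal component held 45.4% of the variance and separated these times. Time in culture and any processing day cannot be told apart here. A second component, with 23.0% of the variance, set vehicle 6 h replicate 1 and 1,25D 48 h replicate 4 apart from the other 11 arrays. Those 2 arrays had the narrowest signal ranges, with interquartile ranges of 3.04 and 2.95 on the log2 scale against 3.27 to 3.46 elsewhere. They were kept in every comparison, and counts without them are given beside the main counts.

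**Figure D1:**
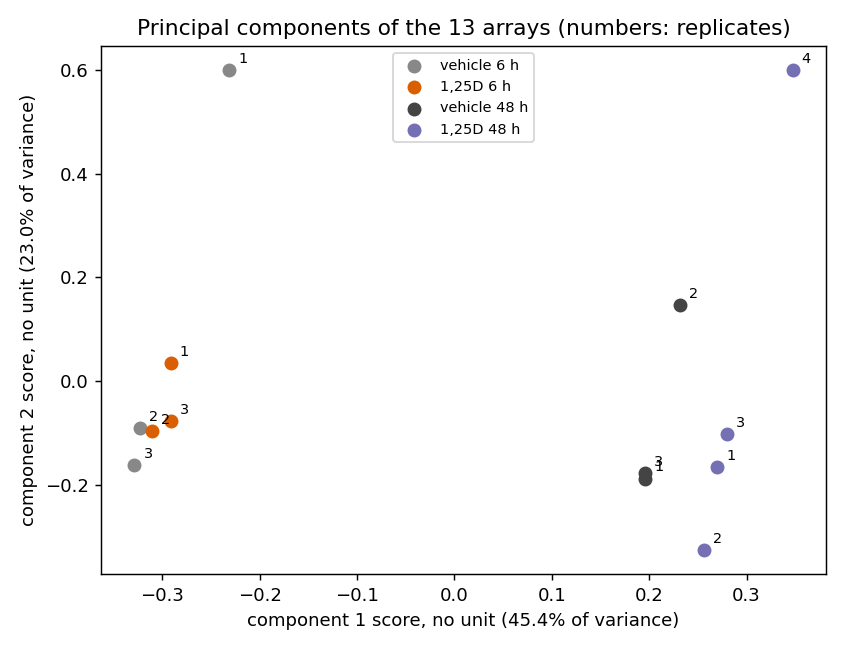
Scores of the 13 arrays on the first and second principal components (no unit; 45.4% and 23.0% of the variance), coloured by group and numbered by replicate. The 6 h arrays lie on the left and the 48 h arrays on the right, and vehicle 6 h replicate 1 and 1,25D 48 h replicate 4 lie apart at the top.

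3 genes were examined array by array: Cyp24a1 as a marker of an active vitamin D receptor, Vdr, and Il1a. Il1a was chosen because the study's authors are known to have followed it up, so its choice was not independent of these data. Direct and indirect effects of the hormone cannot be told apart here. Cyp24a1, which encodes the hydroxylase that starts the breakdown of 1,25D, was 361-fold higher at 6 h and 228-fold higher at 48 h. Its log2 signal was 4.53 ± 0.216 (SD, n = 3) in vehicle and 13.03 ± 0.202 (SD, n = 3) in treated cells at 6 h, and 4.56 ± 0.42 (SD, n = 3) against 12.39 ± 0.155 (SD, n = 4) at 48 h. Vehicle signals lay at the 26.2 and 26.8 percentiles of all probe sets, where background can make up much of the signal, so these folds may understate the change. Il1a, the gene for the cytokine interleukin-1 alpha, went from 6.24 ± 0.074 to 9.02 ± 0.134 at 6 h, a 6.85-fold rise, and from 7.42 ± 0.113 to 9.70 ± 0.0646 at 48 h, a 4.86-fold rise. In each of these comparisons every treated array lay above every vehicle array. Vdr, the receptor gene, was 9.46 ± 0.269 in vehicle and 9.41 ± 0.146 in treated cells at 6 h, and 9.82 ± 0.0426 and 9.71 ± 0.12 at 48 h. By a two-sided exact permutation test, Cyp24a1 and Il1a gave p = 0.1 at 6 h and p = 0.0571 at 48 h, the smallest values that 3 against 3 and 3 against 4 arrays allow, and Vdr gave p = 0.9 and p = 0.229. In the limma fit over all genes, adjusted p for Vdr was 0.979 at 6 h and 1 at 48 h.

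**Figure D2:**
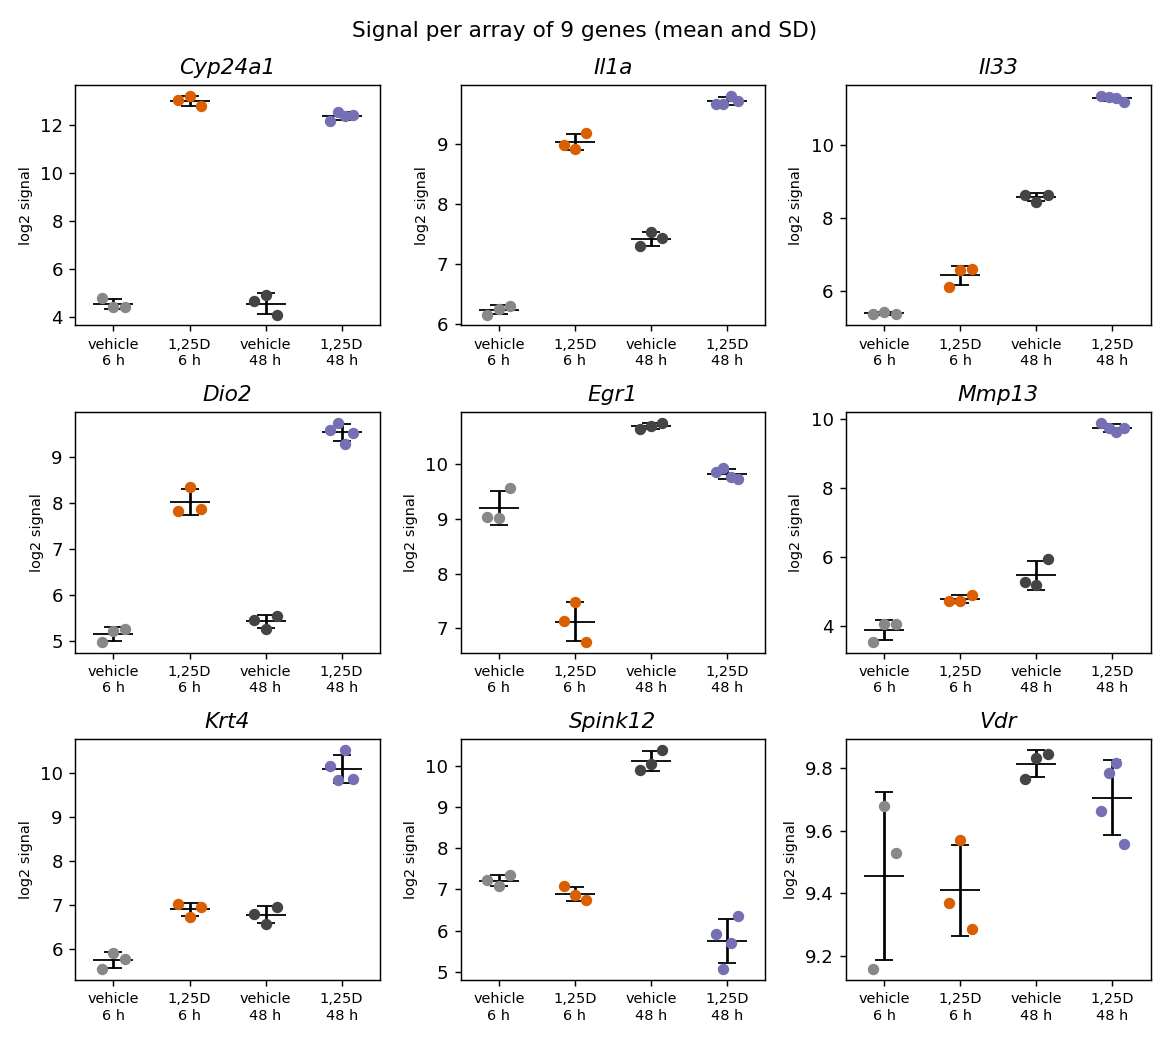
Log2 signal per array of 9 genes in the 4 groups, with 1 point per array and bars for the mean and SD (n = 3, and n = 4 for 1,25D 48 h). Cyp24a1, Il1a, Il33 and Dio2 were higher in treated arrays at both times, Mmp13 and Krt4 were highest in 1,25D 48 h, Egr1 was lower in treated arrays at both times, Spink12 was lowest in 1,25D 48 h, and Vdr overlapped between treated and vehicle arrays at both times.

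The early response to 1,25D, at 6 h, was led by Cyp24a1 (log2 change 8.496, SE 0.20, adjusted p = 3.3e-11). Next came Dio2, the deiodinase that activates thyroid hormone (2.85, SE 0.17, adjusted p = 2.03e-06), Prelp, a matrix proteoglycan (2.84), Il1a (2.78, SE 0.12, adjusted p = 6.78e-08) and Apcdd1, a membrane inhibitor of Wnt signalling (2.69). Vstm5 (2.53), Rnf152 (2.40), the carbohydrate kinase gene Shpk (2.31), the growth factor gene Pdgfb (1.94) and the kallikrein protease gene Klk6 (1.92) completed the 10 largest rises. The largest falls were in Egr1, an immediate early transcription factor (-2.09, SE 0.18, adjusted p = 4.06e-05), the cholesterol hydroxylase gene Ch25h (-1.77), the pentraxin Ptx3 (-1.62), Il6 (-1.56, SE 0.15, adjusted p = 0.000116) and the receptor Tlr2 (-1.53). Cited4 (-1.53), Slc7a2 (-1.37), Atp12a (-1.29), the matrix protease Adamts5 (-1.18) and the protease inhibitor Timp3 (-1.18) followed. Altogether 155 of 18193 genes changed in the limma fit, 125 higher and 30 lower, and 75 and 18 of them by at least 2-fold. In all 155 the treated and vehicle arrays did not overlap, as in 10.2% of all genes, where chance gives 10%. Without the 2 arrays that stand apart the count was 248, 140 higher and 108 lower. Without vehicle 6 h replicate 1 alone it was 174, 117 higher and 57 lower. Without 1,25D 48 h replicate 4 alone it was 185, 149 higher and 36 lower. The latter array is not in the 6 h comparison and acts only through the shared estimate of the spread. The number of falls thus depends on both arrays. Tlr2 was not called without 1,25D 6 h replicate 1 or 3 (adjusted p up to 0.0631). Cited4 was not called without vehicle 6 h replicate 2 or 3 or 1,25D 6 h replicate 1 or 2 (adjusted p up to 0.0802). Adamts5 was not called without vehicle 6 h replicate 2 or 3 or 1,25D 6 h replicate 1 or 3 (adjusted p up to 0.151). Without probe sets that can match several transcripts Prelp was no longer called.

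Among gene lists fixed before the data were examined, the list of prostate luminal and secretory genes held the most calls at 6 h among those that passed camera. In this list, of 22 measured members, 4 rose and 0 fell (5 and 0 adjusted over the list alone): the secreted phosphatase Acpp (1.49), the tight junction protein Cldn4 (1.52), the protease Tmprss2 (1.37) and the keratin Krt19 (0.80). The median log2 change over the list was 0.04, and the list passed camera with the preset correlation alone (adjusted p = 0.000567, and adjusted p = 0.0866 with an estimated correlation). In the basal cell list, of 18 measured members, 0 rose and 1 fell (0 and 2 adjusted over the list alone). The member that fell was the Notch ligand Jag1 (-1.07), and Krt5 changed by -0.36 without passing the test (camera toward lower values, adjusted p = 0.0106, and adjusted p = 0.767 with an estimated correlation). Krt19 was not called without 1,25D 6 h replicate 1 or 3 (adjusted p up to 0.0713). Jag1 was not called without 1,25D 6 h replicate 1 (adjusted p up to 0.0543). The heat shock list was higher as well (adjusted p = 0.04, and adjusted p = 0.195 with an estimated correlation), with Hsph1 (0.69) as its only called member, and without the 2 arrays that stand apart its adjusted p was 0.094. Basal genes did not pass camera without vehicle 6 h replicate 2 or 3. Heat shock genes did not pass camera without vehicle 6 h replicate 1, 2 or 3, 1,25D 6 h replicate 2 or 3, vehicle 48 h replicate 1 or 1,25D 48 h replicate 4.

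Other lists held a few changed genes and did not pass camera at 6 h. In the vitamin D list, of 43 measured members, 2 rose and 0 fell (4 and 1 adjusted over the list alone): Cyp24a1 and the nuclear receptor corepressor Nrip1 (1.14). In the interleukin-1 family list, of 21 measured members, 2 rose and 0 fell (2 and 0 adjusted over the list alone): Il1a and the alarmin gene Il33 (1.03). In the list of NF-kB targets, cytokines and chemokines, of 41 measured members, 2 rose and 2 fell (5 and 9 adjusted over the list alone). The inhibitor Nfkbia (0.78) and the chemokine Cx3cl1 (1.15) rose, whereas Il6 and Ptx3 fell. In the immediate early list, of 27 measured members, 1 rose and 3 fell (4 and 7 adjusted over the list alone), with Egr1, Myc (-0.60) and the matricellular gene Ccn1 (-0.50) lower and Fos (0.57) higher. Among genes of TGF-beta, activin and BMP signalling, of 36 measured members, 2 rose and 1 fell (2 and 2 adjusted over the list alone): Ccn2 (0.81) and the coreceptor Tgfbr3 (1.45) rose and the activin antagonist Fst (-1.01) fell. No member of the G1/S list (46 measured) or of the G2/M list (49 measured) was called at 6 h by limma, and 4 and 0 members had an unadjusted p under 0.05. Among epidermal-type genes, of 32 measured members, 3 rose and 0 fell (4 and 0 adjusted over the list alone), namely Klk6, Krt4 (1.15) and the protease Klk8 (0.72). By camera, adjusted p over these lists ranged from 0.107 for NF-kB targets to 0.926 for G1/S genes. By fry, which asks whether a list moves one way, the vitamin D list (adjusted p = 0.00792) and the interleukin-1 list (adjusted p = 0.0206) were higher, with mean log2 changes of 0.21 and 0.16 but medians of -0.00304 and -0.0397. The list of stem and progenitor cell markers was lower by fry (adjusted p = 0.0206, mean -0.105, median -0.0651) and did not pass camera (adjusted p = 0.0682). Myc was not called without vehicle 6 h replicate 2 or 1,25D 6 h replicate 1 or 2 (adjusted p up to 0.0915). Fos was not called without vehicle 6 h replicate 2 or 1,25D 6 h replicate 1 or 3 (adjusted p up to 0.0985). Ccn1 was not called without vehicle 6 h replicate 3 or 1,25D 6 h replicate 2 or 3 (adjusted p up to 0.0808). Krt4 was not called without 1,25D 6 h replicate 1 or 3 (adjusted p up to 0.0647). Klk8 was not called without vehicle 6 h replicate 3 or 1,25D 6 h replicate 1 or 3 (adjusted p up to 0.142).

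The later response to 1,25D, at 48 h, was again led by Cyp24a1 (log2 change 7.83, SE 0.18, adjusted p = 4e-11). Next came the collagenase Mmp13 (4.28, SE 0.19, adjusted p = 2.09e-08), the cornified envelope gene Sprr2f (4.17), Dio2 (4.10, SE 0.16, adjusted p = 8.88e-09), the kallikrein Klk1b1 (4.09), the cystatin-like protease inhibitor Stfa2l1 (4.04) and the stromelysin Mmp3 (3.49, SE 0.16, adjusted p = 2.27e-08). The coagulation factor gene F13a1 (3.44), the keratin Krt4 (3.31) and Tmigd1 (3.23) also rose. The largest falls were in the protease inhibitor Spink12 (-4.35, SE 0.24, adjusted p = 1.79e-07), the collagen Col11a1 (-3, SE 0.28, adjusted p = 3.65e-05), Bbox1, an enzyme of carnitine synthesis (-2.71), the phospholipase Plb1 (-2.58) and Igfbp5, which binds insulin-like growth factors (-2.55, SE 0.38, adjusted p = 0.00256). Acod1, the enzyme that makes itaconate (-2.51), Wfdc3 (-2.45), the integrin Itga8 (-2.15), Cited4 (-2.05) and Glycam1 (-1.99) followed. The Sprr2, Klk1b, Stfa and Wfdc genes belong to families of closely similar members, so their signals cannot be assigned to 1 member with certainty. By limma 434 genes changed, 261 higher and 173 lower, and 121 and 63 of them by at least 2-fold. Treated and vehicle arrays did not overlap in any of the 434, as in 12.6% of all genes, where chance gives 5.71%. The count fell to 271, 260 and 275 when vehicle 48 h replicate 1, 2 or 3 was left out, and it was 602 without the 2 arrays that stand apart. Without probe sets that can match several transcripts Igfbp5 was no longer called. Itga8 was not called without vehicle 48 h replicate 1 (adjusted p up to 0.0621).

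**Figure D3:**
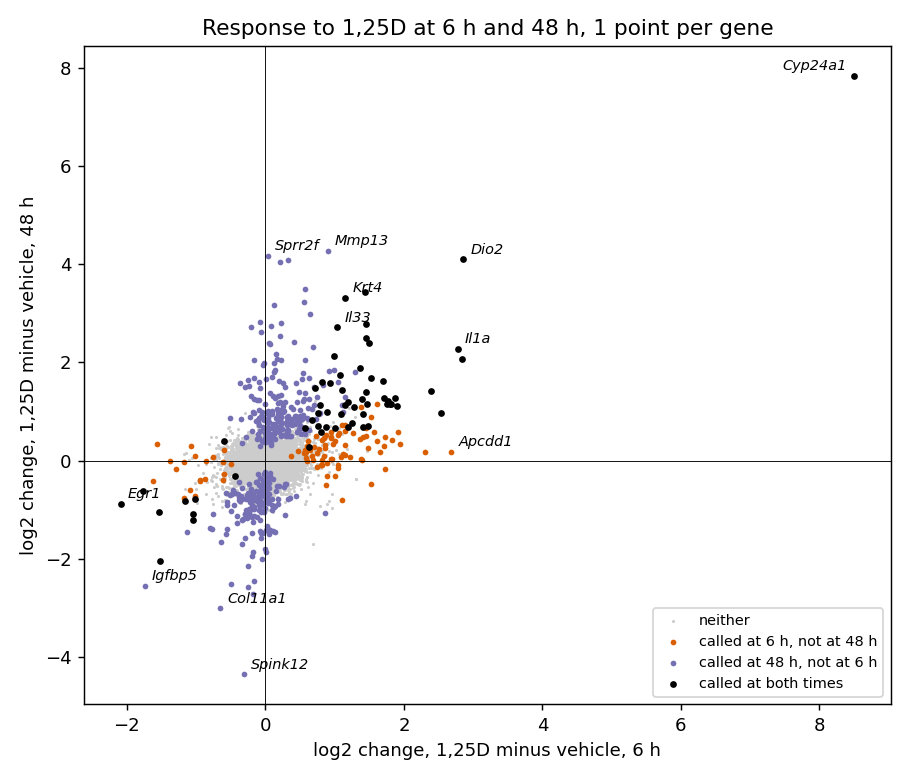
Log2 change with 1,25D at 6 h (x axis) and at 48 h (y axis), with 1 point for each of 18193 genes, coloured by the times at which limma called it. The 50 genes higher at both times lie in the upper right, with Cyp24a1 at 8.496 and 7.83, and most other called genes were called at 1 time only. A call at 1 time only does not show that the response differed between times.

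Genes of epidermal-type differentiation rose together at 48 h: of 32 measured members, 13 rose and 0 fell (19 and 1 adjusted over the list alone). Besides Krt4 they included Sprr2d (2.54), the protease Klk8 (1.48) and the keratin Krt16 (1.51). The list's mean log2 change was 0.78 (camera adjusted p = 3.19e-24, and adjusted p = 0.0235 with an estimated correlation). Without the 2 arrays that stand apart, 16 members were higher and 0 lower. In the prostate luminal list, of 22 measured members, 2 rose and 4 fell (4 and 7 adjusted over the list alone): the simple-epithelium keratins Krt8 (-0.43) and Krt18 (-0.34) and the claudin Cldn3 (-0.47) fell, while Acpp (0.70) was higher (camera adjusted p = 0.101, and adjusted p = 0.299 with an estimated correlation). In the list of stem and progenitor cell markers, of 31 measured members, 1 rose and 2 fell (5 and 3 adjusted over the list alone): Aldh1a1 (-0.70) and Notch1 (-0.73) fell and Klf4 (0.54) rose (camera adjusted p = 0.543, and adjusted p = 0.648 with an estimated correlation). Acpp was not called without vehicle 48 h replicate 2 or 3 (adjusted p up to 0.0642). Cldn3 was not called without vehicle 48 h replicate 2 or 3 (adjusted p up to 0.0699). Aldh1a1 was not called without vehicle 48 h replicate 1 or 3 (adjusted p up to 0.0569). Notch1 was not called without vehicle 48 h replicate 3 (adjusted p up to 0.0744). Klf4 was not called without vehicle 48 h replicate 2 or 3 or 1,25D 48 h replicate 3 (adjusted p up to 0.121).

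As a list, genes of G2/M and mitosis were lower at 48 h, with few single calls. In this list, of 49 measured members, 0 rose and 3 fell (0 and 8 adjusted over the list alone); the 3 were the kinetochore gene Ndc80 (-0.61), Cdc20, an activator of the anaphase-promoting complex (-0.44), and the cyclin Ccna2 (-0.39). The list's mean log2 change was -0.32 (camera adjusted p = 7.38e-17, and adjusted p = 0.0347 with an estimated correlation). Without the 2 arrays that stand apart, 1 member was lower (camera adjusted p = 6.2e-11). Ndc80 was not called without vehicle 48 h replicate 1, 2 or 3 or 1,25D 48 h replicate 1, 3 or 4 (adjusted p up to 0.148). Cdc20 was not called without 1,25D 6 h replicate 1, 2 or 3, vehicle 48 h replicate 1 or 2 or 1,25D 48 h replicate 1, 3 or 4 (adjusted p up to 0.234). Ccna2 was not called without vehicle 6 h replicate 1, 1,25D 6 h replicate 1, 2 or 3, vehicle 48 h replicate 1, 2 or 3 or 1,25D 48 h replicate 1, 2, 3 or 4 (adjusted p up to 0.229). By limma no G1/S gene was called, 6 had an unadjusted p under 0.05, and the mean log2 change was -0.14 (camera adjusted p = 0.001, and adjusted p = 0.184 with an estimated correlation). In the heat shock list, of 16 measured members, 0 rose and 2 fell (0 and 3 adjusted over the list alone), the small heat shock genes Hspb1 (-1.06) and Hspb8 (-0.77), and the list was lower (camera adjusted p = 1.29e-05, and adjusted p = 0.0171 with an estimated correlation). Hspb8 was not called without vehicle 48 h replicate 2 or 3 (adjusted p up to 0.068).

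In the interleukin-1 family list at 48 h, of 21 measured members, 2 rose and 2 fell (3 and 3 adjusted over the list alone): Il33 (2.71, SE 0.13, adjusted p = 4.71e-08) and Il1a (2.28, SE 0.11, adjusted p = 5.7e-08) rose, and the receptor antagonist Il1rn (-0.74) and the adaptor Myd88 (-0.65) fell (camera adjusted p = 0.131, and adjusted p = 0.365 with an estimated correlation). The interleukin-1 list passed camera without the 2 arrays that stand apart (adjusted p = 0.0276). In the NF-kB, cytokine and chemokine list, of 41 measured members, 5 rose and 3 fell (8 and 8 adjusted over the list alone), with Mmp3 and Nfkbiz (0.81) higher and the adhesion molecule Icam1 (-1.08) and the chemokine Ccl20 (-1.09) lower (mean 0.0253, median -0.0491, camera adjusted p = 0.993, and adjusted p = 0.996 with an estimated correlation). Among senescence-associated secretory and marker genes, of 27 measured members, 6 rose and 1 fell (8 and 3 adjusted over the list alone); the members with the smallest p were the proteases Mmp13, Mmp3 and Mmp10 (1.501) and the protease inhibitor Serpinb2 (2.05) (camera adjusted p = 0.000518, and adjusted p = 0.125 with an estimated correlation). In the vitamin D list, of 43 measured members, 6 rose and 2 fell (6 and 2 adjusted over the list alone), among them the transporter Abcc4 (2.04), the claudin Cldn2 (1.66) and the gluconeogenic enzyme Fbp1 (-1.01) (camera adjusted p = 0.0006, and adjusted p = 0.0582 with an estimated correlation). In the antioxidant list, of 33 measured members, 3 rose and 0 fell (9 and 3 adjusted over the list alone): the glutathione genes Gsta4 (1.17) and Gsr (1.00) and the cystine transporter Slc7a11 (1.52) (camera adjusted p = 0.000635, and adjusted p = 0.081 with an estimated correlation). Among genes of TGF-beta, activin and BMP signalling, of 36 measured members, 3 rose and 1 fell (6 and 1 adjusted over the list alone), with Ccn2 (1.59), Tgfbr3 (1.40) and Bmp4 (0.90) higher (camera adjusted p = 0.015, and adjusted p = 0.333 with an estimated correlation). In the growth factor list, of 42 measured members, 5 rose and 2 fell (8 and 2 adjusted over the list alone), with Igf1 (1.07) and Ereg (0.61) higher and Igfbp5 lower (camera adjusted p = 0.0102, and adjusted p = 0.355 with an estimated correlation). Il1rn was not called without vehicle 48 h replicate 1, 2 or 3 or 1,25D 48 h replicate 2 (adjusted p up to 0.136). Myd88 was not called without vehicle 48 h replicate 2 or 3 (adjusted p up to 0.129). TGF-beta genes did not pass camera without 1,25D 48 h replicate 2. Growth factor genes did not pass camera without vehicle 48 h replicate 2. Of 30 lists, 14 passed camera at 48 h with the preset correlation and 3 with an estimated correlation.

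Further lists passed camera at 48 h toward lower values with the preset correlation alone. In the housekeeping list, of 14 measured members, 0 rose and 2 fell (0 and 3 adjusted over the list alone): the transferrin receptor gene Tfrc (-0.45) and the tubulin gene Tubb5 (-0.26) (mean -0.14, camera adjusted p = 0.0391, and adjusted p = 0.15 with an estimated correlation). Among interferon response genes, of 35 measured members, 0 rose and 0 fell (0 and 2 adjusted over the list alone), and 6 had an unadjusted p under 0.05 by limma (mean -0.15, camera adjusted p = 0.00172, and adjusted p = 0.125 with an estimated correlation). Among regulators of epithelial-mesenchymal transition, of 17 measured members, 0 rose and 1 fell (0 and 3 adjusted over the list alone), S100a4 (-0.86) (mean -0.19, camera adjusted p = 0.0214, and adjusted p = 0.0932 with an estimated correlation). By fry these lists were lower too, with adjusted p = 0.00382, 0.013 and 0.00281. Camera adjusted p without the 2 arrays that stand apart was 0.0901, 0.0324 and 0.093. Housekeeping genes did not pass camera without vehicle 48 h replicate 1 or 2 or 1,25D 48 h replicate 3 or 4. Epithelial-mesenchymal transition genes did not pass camera without 1,25D 48 h replicate 4. Tfrc was not called without 1,25D 6 h replicate 1, vehicle 48 h replicate 1, 2 or 3 or 1,25D 48 h replicate 2, 3 or 4 (adjusted p up to 0.192). Tubb5 was not called without vehicle 48 h replicate 1, 2 or 3 or 1,25D 48 h replicate 1, 2 or 3 (adjusted p up to 0.139).

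**Figure D4:**
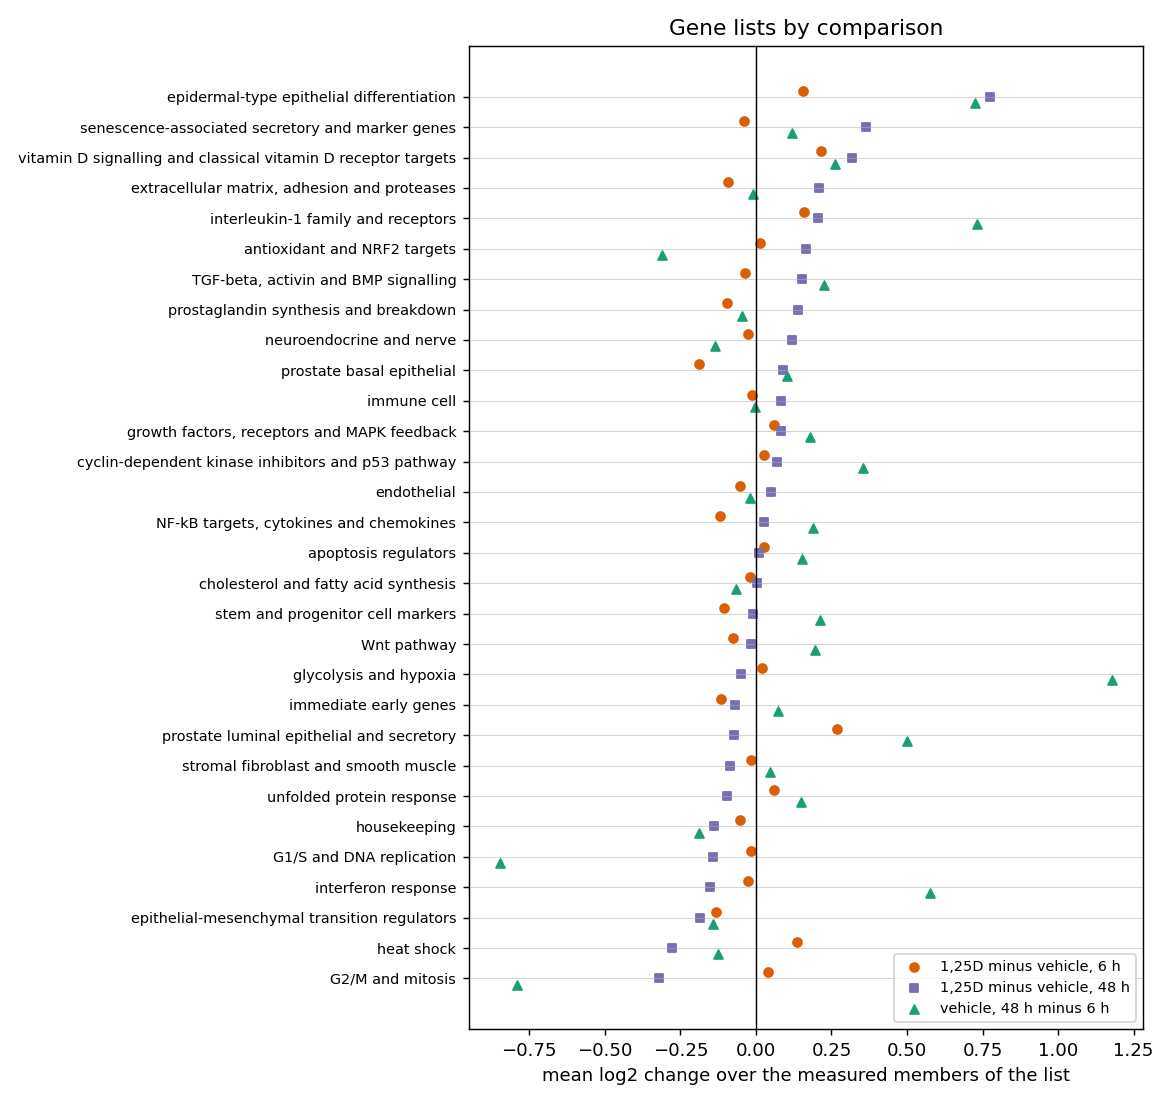
Mean log2 change over the measured members of each of 30 gene lists, for 1,25D against vehicle at 6 h and at 48 h and for vehicle at 48 h against vehicle at 6 h. Epidermal-type genes were highest at 48 h with 1,25D (0.78), and glycolysis and hypoxia genes rose most with time (1.18).

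Few markers of other cell types that such cultures could hold were called. At 6 h none of the stromal (21 measured), immune (27), endothelial (14) or neuroendocrine and nerve (14) markers was called by limma, and 0, 2, 0 and 1 of them had an unadjusted p under 0.05. At 48 h the macrophage-enriched lysosomal gene Cd68 (1.23) and the adhesion molecule gene Ncam1 (0.88) rose and S100a4 (-0.86), which many cell types express, fell, 1 gene in each of 3 of these lists. No endothelial marker was called by limma, and 0 had an unadjusted p under 0.05. Camera adjusted p at 48 h ranged from 0.112 for immune cells to 0.543 for endothelial cells. Adjusted over the list alone, 3 stromal markers fell at 48 h. Without the 2 arrays that stand apart the stromal list was lower by camera at 48 h (mean -0.16, adjusted p = 0.0324) and in the difference between 48 h and 6 h (mean -0.227, adjusted p = 0.003).

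The response at 48 h was compared with that at 6 h gene by gene, as the difference between the log2 changes. Sprr2f (4.13, SE 0.36, adjusted p = 0.000104), Stfa2l1 (3.83), Klk1b1 (3.76), Mmp13 (3.38, SE 0.28, adjusted p = 8.65e-05) and Egfbp2, another kallikrein gene (3.05), rose more at 48 h. Spink12 (-4.03, SE 0.35, adjusted p = 9.96e-05), Bbox1 (-2.52), Apcdd1 (-2.51, SE 0.24, adjusted p = 0.000181), Col11a1 (-2.35) and Plb1 (-2.33) had the most negative differences. Apcdd1 had risen 6.44-fold at 6 h and was at 1.13-fold at 48 h. Il33 rose more at 48 h (1.68, SE 0.19, adjusted p = 0.00078), whereas for Il1a the difference was -0.49 with adjusted p = 0.518. Il6, lower at 6 h, had a difference of 1.90 (adjusted p = 0.000559), and Pdgfb, higher at 6 h, one of -1.60 (adjusted p = 0.00288). In all, 115 genes differed between times by limma, 63 with the higher and 52 with the lower log2 change at 48 h. The count was 66 without 1,25D 6 h replicate 1, 75 without vehicle 48 h replicate 2 and 199 (130 and 69) without the 2 arrays that stand apart. Bbox1 was not called without vehicle 6 h replicate 1, 2 or 3, 1,25D 6 h replicate 1, 2 or 3, vehicle 48 h replicate 1, 2 or 3 or 1,25D 48 h replicate 2 (adjusted p up to 0.144). Col11a1 was not called without vehicle 6 h replicate 1 or 2, 1,25D 6 h replicate 1, 2 or 3 or vehicle 48 h replicate 1, 2 or 3 (adjusted p up to 0.0898). Without probe sets that can match several transcripts Apcdd1 was no longer called.

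Across lists, some epidermal-type genes rose more at 48 h than at 6 h: of 32 measured members, 7 had a positive and 0 a negative difference (14 and 2 adjusted over the list alone), among them Sprr2d (2.33), Krt16 (1.80) and Krt4 (2.16) (camera adjusted p = 7.24e-15, and adjusted p = 0.0538 with an estimated correlation). In the luminal list, of 22 measured members, 0 had a positive and 3 a negative difference (0 and 8 adjusted over the list alone): Cldn4 (-2.00), Cldn3 (-0.77) and Krt18 (-0.34) (camera adjusted p = 8.34e-07, and adjusted p = 0.0107 with an estimated correlation). In the heat shock list, of 16 measured members, 0 had a positive and 1 a negative difference (0 and 5 adjusted over the list alone), with Hsph1 (-0.67) the called member (camera adjusted p = 2.44e-09, and adjusted p = 0.00239 with an estimated correlation). By limma no G2/M gene was called in the difference, where 15 had an unadjusted p under 0.05, and the list as a whole was lower (mean -0.36; camera adjusted p = 7.24e-15, and adjusted p = 0.0506 with an estimated correlation). The other 10 lists that passed camera in the difference did so with the preset correlation alone, with adjusted p from 0.146 to 0.354 with an estimated correlation. Of these, the G1/S (0.464), prostaglandin (0.915), unfolded protein response (0.205) and interferon (0.199) lists did not pass without the 2 arrays that stand apart (adjusted p in parentheses). Krt18 was not called without vehicle 6 h replicate 1 or 3, 1,25D 6 h replicate 1 or 3, vehicle 48 h replicate 1, 2 or 3 or 1,25D 48 h replicate 1, 3 or 4 (adjusted p up to 0.0987). Hsph1 was not called without vehicle 6 h replicate 1 or 2, 1,25D 6 h replicate 1 or 2, vehicle 48 h replicate 1 or 3 or 1,25D 48 h replicate 1 or 3 (adjusted p up to 0.0844).

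Of the genes called at 6 h, 50 of 125 higher genes were also higher at 48 h and 9 of 30 lower genes were also lower, where independent lists would share 1.79 and 0.285. Whether or not they were called at 48 h, 112 of the 125 and 22 of the 30 had the same sign there. The 2 times share no arrays, but both were tested with the same estimate of the spread per probe set. The calls are therefore not independent, and the expected numbers are only a rough guide. Plk2, a kinase gene named here because it was the only gene called in opposite directions, and so chosen after its values were seen, went from -0.60 at 6 h to 0.41 at 48 h. Its call at 6 h ended without 1,25D 6 h replicate 1 (adjusted p = 0.0543). Its call at 48 h ended without 1,25D 6 h replicate 1 or 2, vehicle 48 h replicate 1, 2 or 3 or 1,25D 48 h replicate 1, 2, 3 or 4 (adjusted p up to 0.202). Across genes, which are not independent replicates, the responses at 6 h and 48 h correlated with Pearson's r = 0.297 and Spearman's rho = 0.0674.

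Vehicle arrays themselves differed between 6 h and 48 h, which sets the background for the hormone's effect. In this comparison, changes with time in culture cannot be told apart from those of any processing day. The cytokine gene Tslp (5.03, SE 0.15, adjusted p = 3.04e-10), the surfactant protein gene Sftpd (4.92, SE 0.13, adjusted p = 1.66e-10), Ifit1bl1 (4.69), Sprr2d (4.68) and the oxygen sensor gene Egln3 (4.43) rose most. Ccnb1ip1 (-3.48, SE 0.24, adjusted p = 4.96e-07), Pcolce2 (-3.31), Snhg3 (-2.27), Trmt61a (-2.26) and the transporter Abcc4 (-2.23) fell most. Genes of proliferation fell together. In the G1/S list, of 46 measured members, 0 rose and 36 fell (0 and 42 adjusted over the list alone), such as Rrm2 (-1.19) and Mcm7 (-0.79) (camera adjusted p = 1.22e-23, and adjusted p = 0.00595 with an estimated correlation). In the G2/M list, of 49 measured members, 0 rose and 42 fell (0 and 45 adjusted over the list alone), such as Ccna2 (-1.21), Aurka (-1.15) and Plk1 (-1.22) (camera adjusted p = 2.08e-23, and adjusted p = 0.0121 with an estimated correlation). Limma called 3382 genes, 1790 higher and 1592 lower, and in 3358 of them the arrays did not overlap, as in 31% of all genes, where chance gives 10%. Without the 2 arrays that stand apart the count was 4347, 1971 higher and 2376 lower.

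Glycolysis and hypoxia genes rose with time: of 32 measured members, 21 rose and 1 fell (23 and 1 adjusted over the list alone), led by Aldoc (3.75), Bnip3 (3.70) and Ndrg1 (2.02) (camera adjusted p = 1.3e-16, and adjusted p = 0.0217 with an estimated correlation). Interferon response genes rose too: of 35 measured members, 19 rose and 0 fell (22 and 0 adjusted over the list alone), with Ifi35 (0.96) and Ifih1 (1.92) among them (camera adjusted p = 2.74e-10, and adjusted p = 0.0121 with an estimated correlation). In the interleukin-1 family list, of 21 measured members, 11 rose and 1 fell (11 and 1 adjusted over the list alone), including Il33 (3.18), Il18 (2.71) and Il1rn (1.89) (camera adjusted p = 5.35e-06, and adjusted p = 0.0217 with an estimated correlation). In the luminal list, of 22 measured members, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with Krt19 (2.02), Cldn4 (1.78), Acpp (1.54) and Psca (2.35) higher (camera adjusted p = 0.000277, and adjusted p = 0.0217 with an estimated correlation). In the epidermal-type list, of 32 measured members, 10 rose and 0 fell (13 and 0 adjusted over the list alone), with Sprr1a (3.39) and S100a9 (2.53) after Sprr2d (camera adjusted p = 2.82e-06, and adjusted p = 0.182 with an estimated correlation). In the antioxidant list, of 33 measured members, 6 rose and 13 fell (6 and 15 adjusted over the list alone): Srxn1 (-1.59) and Txnrd1 (-1.40) fell and the metallothionein Mt1 (0.85) rose (camera adjusted p = 0.02, and adjusted p = 0.182 with an estimated correlation). The vitamin D list (adjusted p = 0.02, and adjusted p = 0.178 with an estimated correlation) and the list of cyclin-dependent kinase inhibitors and p53 pathway genes (adjusted p = 0.02, and adjusted p = 0.182 with an estimated correlation) were higher with time by camera. The vitamin D list did not pass without the 2 arrays that stand apart (adjusted p = 0.0796). Vitamin D genes did not pass camera without vehicle 6 h replicate 1 or vehicle 48 h replicate 3. Kinase inhibitor and p53 pathway genes did not pass camera without vehicle 48 h replicate 3.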

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

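Tests of the pattern of epidermal-type genes, and the tests of exchanged labels over called genes, over Cyp24a1 and over genes that change with time, were chosen after their results or close variants of them had been seen. The other tests in this part were set beforehand, though the prediction for cells of another type did not include bootstrap spreads. The planned test of exchanged labels, over all probe sets, was run only after the results of other forms over called genes had been seen. Those forms put both arrays closest to their own groups and were set aside, the first because its genes had been called with those arrays included and the other because the distances of the vehicle array were nearly tied.

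Vehicle 6 h replicate 1 and 1,25D 48 h replicate 4, in different groups and times, deviated from their groups alike (r = 0.745 across probe sets). Vehicle 48 h replicate 2 shared part of this deviation (r = 0.592 and 0.651 with the 2 arrays), and without all 3 arrays 227 genes were called at 6 h and 435 at 48 h, against 248 and 602 without the 2. A compressed signal range accounts for little of this, since after a smooth trend on signal level was removed the correlation was still 0.703. Exchanged treatment labels are excluded by Cyp24a1, which lay at least 7.51 log2 units from the nearest array of the other treatment in both. Exchanged time labels are excluded too: of genes that changed at least 4-fold between times in the fit without the 2 arrays, 97.5% and 96.8% lay closer to the own time. So although over all probe sets both arrays (2) lay closer to the other treatment at their own time than to their own group, and as few as 67.7% of the genes called without them lay closer to the own group, no exchange between the 4 groups is left, while an exchange with a sample outside the series was not tested. Cells of another type stay open. Endothelial markers reached the 92.2 and 98.7 percentiles of random lists in the 2 arrays, and stromal markers 90.3 and 92. Immune markers reached only 77.1 and 61.4 and nerve markers 42.8 and 90.9. The prediction set beforehand asked for a list above 95 in both arrays, and no list met it, which by that prediction counts against such cells. Bootstrap spreads of 8.22 to 33 points over the lists, which were not part of the prediction, are too wide to settle it. The most abundant endothelial marker, Egfl7, had log2 signals of 8.10 and 8.70 against 7.23 to 7.42 and 7.97 to 8.15 in the other arrays of the groups, while the most abundant stromal marker, Vim, was inside its group's range in both, and the most abundant nerve marker, Mbp, was below its group's range in both. Of the markers, 4 stromal and 0 endothelial ones are also in another list, and which of them these cells express themselves is not known without detection calls. No other biological explanation was tested.

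In the epidermal-type list, 7 of 32 members rose more at 48 h than at 6 h, and the list passed camera with the preset correlation but not with an estimated one (adjusted p = 0.0538). The 2 arrays that stand apart do not account for it, as 8 members were called without them. Probe sets shared between Sprr and Klk paralogs do not account for all of it, as 4 called members (Krt4, Krt6a, Krt16 and S100a8) belong to neither family. A general advance along the change of vehicle cultures with time was tested with glycolysis and hypoxia genes alone. In the ratio of the epidermal-type list they would have risen by 1.26 (SE 0.27) in the mean. Their measured mean at 48 h was -0.0487, which argues against an advance of all lists in that ratio. The hormone response at 48 h and the change with time both use the vehicle 48 h arrays. Sharing them pushes the 2 means of a list toward opposite signs, and the SE treats them as independent. Other lists that passed camera with time were mixed. G2/M (-0.791 with time, -0.321 with the hormone at 48 h), G1/S (-0.848, -0.142), interleukin-1 (0.732, 0.205), vitamin D and kinase inhibitor means kept direction. Luminal (0.5, -0.0723), antioxidant (-0.31, 0.166) and interferon (0.576, -0.153) means did not. A partial advance stays open. No biological explanation was tested.

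Other splits of the arrays were fitted for each count of genes. At 48 h, 1 of 35 splits, the real one, gave 434 genes, and the highest other gave 47, so the share of splits with as many genes was under 0.05. For the difference between times, 1 of 100 relabellings of treatment within times, the real one, gave 115 genes, and the highest other gave 28, so chance can be excluded. At 6 h (155 genes, highest other 4; 1 of 10 splits as large) and with time in vehicle (3382 genes, highest other 0; 1 of 10), the 10 splits are too few for a share under 0.05.

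The test of the difference between times, over all genes, singled out 115 genes. Those named were Sprr2f (4.13), Stfa2l1 (3.83), Klk1b1 (3.76), Mmp13 (3.38), Egfbp2 (3.05), Spink12 (-4.03), Bbox1 (-2.52), Apcdd1 (-2.51), Col11a1 (-2.35), Plb1 (-2.33). Among lists, it singled out with an estimated correlation the luminal list (mean -0.34) and the heat shock list (mean -0.41).

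In 1,25D 48 h, the group of 4, 1 array lay far from the other 3 in 10 of 175 genes examined, where about 1 in 20, or 8.75, are due by chance. Replicate 4, which is also 1 of the 2 arrays that stand apart, was far from the others in Col11a1 (6.61 against 7.78 to 7.84), Dnaja1 (11.72 against 11.52 to 11.54), Hspb8 (8.48 against 8.88 to 8.95), Itga8 (5.45 against 6.62 to 6.78), Serpinb2 (7.01 against 7.49 to 7.51), Trmt61a (6.10 against 6.78 to 6.88), all as log2 signals. Replicate 2 was far from the others in Bmp4 (10.64 against 10.89 to 10.92), Cldn4 (10.94 against 11.37 to 11.44), Ptgs2 (12.14 against 11.43 to 11.53), Tlr2 (9.56 against 8.93 to 9.02).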

How the results depend on the processing

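The added alternatives were chosen after the data were seen: an offset of 16 and leaving out the 2 arrays that stand apart, with or without vehicle 48 h replicate 2. The count at 6 h (155) was 68 with only the 2 groups compared, which leaves fewer arrays to estimate the spread, and 248 without the 2 arrays that stand apart. With array quality weights the count at 48 h (434) was 1043 and that of the difference (115) was 262; without the 2 arrays the difference had 199. The cause of these rises was not tested. The share of higher genes at 6 h was 80.6%, 65.8% with array weights and 56.5% without the 2 arrays. Leaving out each array in turn gave 104 to 185 genes at 6 h, 260 to 500 at 48 h, 66 to 130 for the difference (140 without the 2 arrays and vehicle 48 h replicate 2) and 2540 to 3679 with time, and 1 to 4, 11 to 15, 11 to 14 and 8 to 12 lists. With an estimated correlation, camera called 0 lists at 6 h (3 in the main test), 3 at 48 h (14), 2 in the difference (14) and 6 with time (10). By limma's fry it was 5 at 6 h, 8 in the difference and 18 with time. At 6 h the estimated correlation gave 0 lists at adjusted p under 0.05, and 3 at an unadjusted p under 0.05. The other alternatives that use all 13 arrays kept these counts within 1.5-fold.

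The labels do not say that same-numbered arrays share more than a number. Of 9 same-number pairs, 4 had deviations correlated over 0.1, and all 9 ranged from -0.534 to 0.482. Different-number pairs ranged from -0.478 to 0.651. Treated and vehicle pairs of the same number had 0.277, 0.222 and 0.0692 at 6 h and -0.00941, -0.534 and 0.386 at 48 h. Vehicle pairs between times had -0.243, -0.339 and 0.482. Pairing by number is thus neither shown nor excluded. With the replicate number as a block the counts were 156 at 6 h, 373 at 48 h, 103 for the difference and 3415 with time, and 2, 15, 12 and 10 lists.

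Over 235 results of named genes and 6533 values under alternatives, 6143 kept direction and side of the threshold, 303 fell short of it, 87 newly passed and 0 reversed. For the lists it was 3269 of 3450, with 121, 60 and 0. Of named calls, 28 of 39 at 6 h, 50 of 73 at 48 h, 18 of 25 in the difference and 44 of 44 with time held with each array left out. Signal near background limits the size of folds of dim genes, such as Cyp24a1 in vehicle.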

Other observations

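A few members of the prostaglandin, Wnt, matrix and cyclin-dependent kinase inhibitor lists, fixed beforehand, were called at 48 h, and none of these lists passed camera with an estimated correlation. In the prostaglandin list, of 20 measured members, 2 rose and 1 fell (4 and 1 adjusted over the list alone): the cyclooxygenase gene Ptgs2 (1.05) and the phospholipase gene Pla2g4a (0.88) rose and the receptor gene Ptger4 (-1.20) fell (camera adjusted p = 0.0464, and adjusted p = 0.448 with an estimated correlation). In the Wnt list, of 31 measured members, 2 rose and 1 fell (2 and 4 adjusted over the list alone): the inhibitor Wif1 (1.96) and Wnt4 (0.70) rose and the receptor Fzd7 (-1.44) fell (camera adjusted p = 0.881, and adjusted p = 0.929 with an estimated correlation). Among matrix, adhesion and protease genes, of 42 measured members, 5 rose and 1 fell (10 and 1 adjusted over the list alone), with Mmp13 (4.28), Mmp3 (3.49) and the laminin gene Lama3 (0.88) higher and Adamts1 (-1.08) lower (camera adjusted p = 0.0218, and adjusted p = 0.333 with an estimated correlation). Among cyclin-dependent kinase inhibitors and p53 pathway genes, of 27 measured members, 3 rose and 0 fell (4 and 0 adjusted over the list alone), Gadd45a (1.09), Plk2 (0.41) and Phlda3 (0.55) (camera adjusted p = 0.0819, and adjusted p = 0.333 with an estimated correlation). Prostaglandin genes did not pass camera without vehicle 6 h replicate 2, 1,25D 6 h replicate 2, vehicle 48 h replicate 3 or 1,25D 48 h replicate 4. Matrix genes did not pass camera without vehicle 48 h replicate 2. Camera adjusted p, without the 2 arrays that stand apart, was 0.873 for the prostaglandin list and 0.03 for the cyclin-dependent kinase inhibitor list. Pla2g4a was not called without vehicle 48 h replicate 2 or 3 (adjusted p up to 0.118). Wnt4 was not called without vehicle 48 h replicate 1, 2 or 3 or 1,25D 48 h replicate 1 or 3 (adjusted p up to 0.0881). Fzd7 was not called without vehicle 48 h replicate 1, 2 or 3 or 1,25D 48 h replicate 2 (adjusted p up to 0.132). Lama3 was not called without vehicle 48 h replicate 2 or 3 (adjusted p up to 0.0736). Gadd45a was not called without 1,25D 6 h replicate 1, vehicle 48 h replicate 1 or 2 or 1,25D 48 h replicate 1 or 3 (adjusted p up to 0.188). Phlda3 was not called without vehicle 6 h replicate 2, 1,25D 6 h replicate 1 or 3, vehicle 48 h replicate 1, 2 or 3 or 1,25D 48 h replicate 1, 3 or 4 (adjusted p up to 0.269).

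The 10 genes with the largest falls at 48 h had all risen with time in vehicle cultures, and all 10 of these rises were called. Of the 10 with the largest rises at 48 h, 3 had fallen with time (1 called) and 7 had risen (3 called). This tally and the genes named next were chosen after their values were seen. Abcc4 fell with time (-2.23) and was higher with 1,25D (2.04), and Mmp3 fell with time (-1.55) and was higher with 1,25D (3.49), whereas Igfbp5 rose with time (3.77) and was lower with 1,25D (-2.55). Both comparisons use the vehicle 48 h arrays, which alone push them apart: over all genes the covariance of the changes was -0.0032, against -0.0177 in 100 simulations with no effect, and the correlation was -0.0229 against -0.534. The measured covariance was thus less negative than the simulated one, by 0.0145. The simulated noise was equally wide in all arrays. Real deviations from the group had an SD of 0.202 to 0.246 in vehicle 48 h arrays. In vehicle 6 h replicate 1 and 1,25D 48 h replicate 4 it was 0.445 and 0.46. The simulated covariance may therefore be too negative a reference. The simulation held no real changes, which widen the measured spread, so the correlations cannot be compared directly. Whether 1,25D opposes time over all genes beyond the shared arrays is thus not settled by these values. The tally itself was not tested against the effect of the shared arrays.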
